A study of Mus musculus with 6 samples.

How the data were processed

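The data are 6 one-colour whole mouse genome arrays, 2 for each of 3 gates of CD45-negative EpCAM-positive thymic epithelial cells, each from a pool of 6 mice aged 4 weeks. Per the labels, 10 ng of RNA was amplified and labelled with Cy3. Per the file headers, the scans were read with Agilent Feature Extraction 9.5.3.1, with probe positions on mm9, and the signal is an intensity after background subtraction and detrending within the array, not scaled between arrays. For 15.5% to 28.2% of the spots on an array, the software put a surrogate value in place of the measured signal. This share was highest on Meis1-negative replicate 1 (28.2%) and Meis1-high replicate 1 (26.9%). The deposited value table of the authors is on a log2 scale, scaled per array and centred on each probe's median, so that 100% of its probes have a median of 0 and higher values mean higher signal. Its 41252 entries include the 41174 probes of the scanner files, and its columns correlate with the scaled scanner signals at 0.99989 or above.

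Control spots were left out, which left 43379 spots per array. Of these, the 53 to 78 spots per array that the scanner software marked as outliers were left out too. The rest were averaged per probe, and 40 probes had a missing value after the outlier marks were applied. Each array's 75th percentile was subtracted on the log2 scale. A probe is well above background where the scanner's own mark says so, a mark that the file headers tie to 13 times the SD of the background. Probes so marked on both arrays of at least 1 gate were tested, which kept 26569 probes and left out 14605. Gene names were updated through the accession table for 26690 probes, listed accessions for 105, symbols for 5122 and synonyms for 929, and 8328 kept the name in the files, giving 28030 genes. The probe with the highest mean represented a gene, which gave 18205 genes.

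Groups were compared in R 4.3.3 with limma 3.58.1, with 1 mean per gate over all 6 arrays (3 residual degrees of freedom, prior degrees of freedom 4.36). Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, for 3 comparisons and a moderated F test. The 39 lists of genes, with 767 of 770 members on the array, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The lists, tests, gene rule and alternative settings were chosen before the data were examined, except the settings and tests that the closing section names as added later. The rule for naming genes took, per comparison, the 8 largest rises and falls among called genes (there were none), up to 4 members with the smallest p of each list described, and 13 fixed genes. Genes named outside this rule are said to be so. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3.

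The signal at the 75th percentile was 73.3 and 136.5 in Meis1-high, 158.6 and 163.8 in Meis1-low, and 114.2 and 165.2 in Meis1-negative. Per the file headers, replicate 1 of all gates shared a slide and a scan, as did replicate 2, so slide, scan and replicate number are the same block. Replicate differences correlated across genes at 0.209 between Meis1-high and Meis1-low, 0.128 between Meis1-high and Meis1-negative, and 0.125 between Meis1-low and Meis1-negative. The fit without the block was planned, and the labels state no pairing of the pools.

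The test was tried on simulated data for the comparison of Meis1-high with Meis1-negative, with the real gene count and 200 changed genes. The spread of each gene was the moderated one pooled over all 6 arrays, equal in every gate. The real gates differ in spread, with a median SD within the gate of 0.761 in Meis1-negative, 0.475 in Meis1-high and 0.413 in Meis1-low. It called 0 of 50 genes with a true log2 size of 1, 0 of 50 with 2, 26 of 50 with 4 and 47 of 50 with 6, with 3 unchanged genes called, and 0 genes in a comparison without change. Among 40 simulated lists of 20 genes, camera with the preset correlation called 10 of 10 lists shifted by 1 and 0 others, and with an estimated correlation it called 0. The simulated genes varied independently of each other. The trial therefore cannot tell whether the preset correlation holds for real lists, whose members can vary together.

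Alternatives were normexp background correction (offset 50), quantile and median scaling, no filter and a filter on 4 arrays, a floor at the lowest signal well above background, the block, means of probes, every probe, array weights, a variance trend with robust fitting, the authors' values, an adjusted p under 0.10, a 2-fold minimum, outlier spots kept, the 4 compared arrays alone and each array left out in turn. Median scaling moves the median log2 difference of all genes between Meis1-high and Meis1-negative from -0.10 to -0.20, a shift of -0.102. Percentiles of list medians come from 10000 random lists matched on mean level, whose members were drawn independently of each other. No group holds enough arrays for an outlier test or for other splits of the samples.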

Results

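Gene expression was measured in thymic epithelial cells (TEC), the stromal cells that support and select developing T cells, from 4-week-old mice with an EGFP reporter under Meis1 regulatory sequence. Meis1 is a homeodomain transcription factor of the TALE family. TEC without the leukocyte antigen CD45 and with the adhesion molecule EpCAM were divided into 3 gates. The Meis1-high gate took small cells with bright EGFP, the Meis1-low gate large cells with intermediate EGFP, and the Meis1-negative gate small cells without EGFP. Each gate was sampled from 2 pools of 6 mice, giving 6 one-colour arrays, with replicate 1 of every gate on slide 1 and replicate 2 on slide 2. Levels are log2 signals relative to the array's own 75th percentile, and lists of genes were fixed before the data were examined.

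The 75th percentile of the signal ranged from 73.3 on Meis1-high replicate 1 to 165.2 on Meis1-negative replicate 2, and between 53.1% and 69.6% of the spots on an array were well above background. Replicate arrays correlated across 18205 genes with a Pearson r of 0.904 in Meis1-high, 0.921 in Meis1-low and 0.839 in Meis1-negative, where genes are not independent replicates. Between the 2 Meis1-negative arrays, 4117 genes differed by over 4-fold, against 1728 in Meis1-high and 1240 in Meis1-low. Thymocyte and T cell markers set these 2 arrays apart: 18 of 21 measured markers were higher on replicate 1, by a median of 4.46 on the log2 scale. On the same array, the 27 epithelial junction and keratin genes lay below replicate 2 by a median log2 difference of -1.95. Of 3 genes chosen after their values were seen, Dntt, the terminal transferase of immature lymphocytes, had a level of 9.55 on replicate 1 and 3.17 on replicate 2. Cd3e, a chain of the T cell receptor complex, had levels of 6.82 and 1.12, and the recombinase gene Rag1 5.64 and 0.42. The CD45 gene Ptprc had a level of 4.17 ± 1.41 (SD, n = 2) in Meis1-negative, -0.16 ± 0.75 in Meis1-high and -0.29 ± 1.01 in Meis1-low. The number of arrays, 2 per gate, limits the precision of every value.

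The reporter follows Meis1, so the level of Meis1 itself checks the gates. The Meis1 probe (mm9, chromosome 11, 18911247 to 18911306) had levels of 0.24 and 0.12 on the Meis1-high arrays, -2.35 and -1.61 on the Meis1-low arrays, and -3.21 and -0.99 on the Meis1-negative arrays. The log2 difference of Meis1 was 2.28 ± 0.84 (SE, n = 2 per gate) between Meis1-high and Meis1-negative, with an adjusted p = 0.422 in limma. Both slides gave this direction, 3.44 on slide 1 and 1.11 on slide 2. The difference of Meis1 between Meis1-high and Meis1-low was 2.16 ± 0.84 (adjusted p = 0.349), with 2.59 and 1.73 on the slides. Between Meis1-low and Meis1-negative, Meis1 differed by 0.12 ± 0.84 (adjusted p = 0.980), and the slides gave 0.86 and -0.62. None of these differences passed the threshold. Left-out arrays moved the first from 1.17 without Meis1-negative replicate 1 to 3.38 without Meis1-negative replicate 2 (adjusted p = 0.0453).

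**Figure D1:**
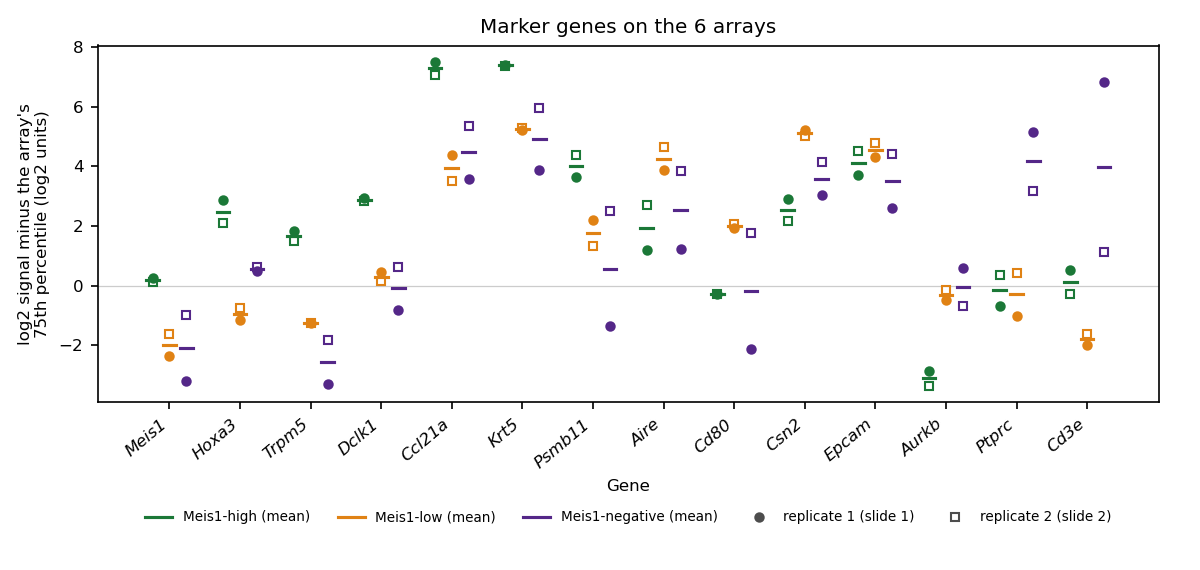
Marker genes on each of the 6 arrays, as log2 signal minus the array's 75th percentile, with filled circles for replicate 1, open squares for replicate 2 and bars for the gate means. Meis1, Trpm5 and Dclk1 lie highest on both Meis1-high arrays, Csn2 and Aire on both Meis1-low arrays, and Ptprc on both Meis1-negative arrays.

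The comparison of Meis1-high with Meis1-low cells asks what separates small TEC of bright reporter signal from large TEC of intermediate signal. Cell size and reporter level cannot be told apart in it. Lists of tuft-like, basal medullary and cortical epithelial genes were higher in Meis1-high, and lists of tissue-restricted antigens, mature medullary genes and cell cycle genes were higher in Meis1-low, by camera at its preset correlation. For each of them, the adjusted p = 0.749 with an estimated correlation. In the simulated trial that setting called 0 of 10 lists truly shifted by 1. Its failure to call a list therefore cannot tell whether a shift of that size is absent, here or in the other comparisons. All 17 measured tuft-like genes, named for chemosensory epithelial cells, were higher in Meis1-high, with a median log2 difference of 2.20 (SD over members 1.01). Of 23 measured Aire-induced tissue-restricted genes, 22 were lower in Meis1-high on both slides, with a median of -2.59 (SD over members 1.26). Neither list rests on the Meis1-negative arrays.

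The tuft-like list rose in Meis1-high by 2.10 on slide 1 and 2.26 on slide 2 (camera adjusted p = 2.8e-08). Its adjusted p = 0.749 with an estimated correlation, and 5 members passed when adjusted over the list alone, against 0 over all genes tested. Among its members, Sh2d6 differed by 3.65 ± 0.73 (SE, n = 2 per gate), Plcb2, a phospholipase of taste transduction, by 3.36 ± 0.62, and Trpm5, the cation channel of the same pathway, by 2.91 ± 0.70. The kinase gene Dclk1 differed by 2.58 ± 0.69, and the adjusted p of these genes in limma lay between 0.249 and 0.254. The list of immature medullary (mTEC-low) and basal epithelial genes also rose, with 12 of 15 members higher and a median of 1.75 (1.36 and 2.09 on the slides, camera adjusted p = 2.1e-04, adjusted p = 0.749 with an estimated correlation). Lifr, a cytokine receptor, differed by 3.72 ± 0.79, the basal keratin Krt5 by 2.13 ± 0.79 and Bcam, a laminin receptor, by 3.25 ± 0.91. Ccl21a, a chemokine that draws thymocytes to the medulla, differed by 3.34 ± 0.79, with a probe that cannot separate it from near-identical copies of the gene. Tnfrsf11b, the decoy receptor for RANKL, lay in the opposite direction at -2.53 ± 0.89.

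Cortical (cTEC) genes rose in Meis1-high, with 13 of 19 members higher and a median of 0.86 (0.38 and 1.33 on the slides, camera adjusted p = 3.2e-04, adjusted p = 0.749 with an estimated correlation). Their median was 0.37 without Meis1-low replicate 2. Fgfr2, a receptor for fibroblast growth factors, differed by 3.07 ± 0.69, Igfbp5 by 3.03 ± 0.70 and the transcription factor gene Scx by 3.24 ± 0.87, while Psmb11, the thymoproteasome subunit, differed by 2.24 ± 1.20 (adjusted p = 0.486). Extracellular matrix and adhesion genes rose by a median of 0.99, 27 of 31 being higher (camera adjusted p = 1.4e-04, adjusted p = 0.749 with an estimated correlation), among them the laminin gene Lamb1 at 2.60 ± 0.68. Interferon response genes rose by a median of 1.11, 17 of 22 being higher (camera adjusted p = 2.1e-04, adjusted p = 0.749 with an estimated correlation), with Ifi44 at 2.18 ± 0.66 and Isg15 at 2.04 ± 0.64. Of the TALE and Hox cofactor genes, 8 of 9 were higher, the list rising by a median of 0.89 (camera adjusted p = 0.0053, adjusted p = 0.749 with an estimated correlation), 0.51 without Meis1-low replicate 1. The list includes Meis1 itself, whose reporter set the gates. Hoxa3, a homeobox gene of thymus development (chromosome 6, 52119744 to 52119803), differed by 3.43 ± 0.62, with an adjusted p = 0.249. Dissociation stress genes, which respond to handling of tissue, rose by a median of 0.70 with 24 of 27 higher (camera adjusted p = 4.4e-04, adjusted p = 0.749 with an estimated correlation), Fos at 1.63 ± 0.60 and Socs3 at 2.55 ± 0.77.

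Aire-induced tissue-restricted genes, products of other organs whose transcription in medullary TEC needs the regulator Aire, fell in Meis1-high by -2.47 on slide 1 and -2.29 on slide 2 (camera adjusted p = 2.5e-07, adjusted p = 0.749 with an estimated correlation), with 4 members passing when adjusted over the list alone. The milk protein gene Csn2 differed by -2.59 ± 0.67, the hormone gene Sst by -3.65 ± 0.93 and S100a8 by -3.07 ± 0.75. Tissue-restricted genes that do not need Aire fell as well, with 12 of 16 lower and a median of -2.09 (camera adjusted p = 5.2e-04, adjusted p = 0.749 with an estimated correlation), among them Apoc3 at -2.74 ± 0.64 and Calca at -2.77 ± 0.65. Genes of mTEC maturation fell by a median of -1.04, with 20 of 21 lower (camera adjusted p = 5.4e-04, adjusted p = 0.749 with an estimated correlation). Examples were Tnfrsf9 at -2.43 ± 0.75 and Hdc at -2.39 ± 0.74, while Aire differed by -2.32 ± 0.996 (adjusted p = 0.387) and the costimulatory ligand gene Cd80 by -2.25 ± 1.17 (adjusted p = 0.474). All 13 microfold-like genes were lower, the list falling by a median of -1.11 (camera adjusted p = 0.0036, adjusted p = 0.749 with an estimated correlation), with the chemokine gene Ccl20 at -2.57 ± 0.87. Cell cycle genes fell by a median of -1.29, 31 of 32 being lower on both slides (camera adjusted p = 3.1e-06, adjusted p = 0.749 with an estimated correlation). The ubiquitin ligase gene Ube2c differed by -1.83 ± 0.62, and the mitotic kinase gene Aurkb by -2.79 ± 0.69, although its probe was well above background on only 1 of the 2 Meis1-high arrays.

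Markers of several other cell types were higher in Meis1-low too. Fibroblast and pericyte markers, a list not called in this comparison, lay the other way (median -0.88, Meis1-low minus Meis1-high). Erythroid markers were lower in Meis1-high for 9 of 9 genes, with a median of -1.93 (-3.13 and -1.93 on the slides, -3.08 without Meis1-high replicate 2) and a camera adjusted p = 7.5e-05. Dendritic cell and macrophage markers were lower for 16 of 17 genes, with a median of -1.83 and a camera adjusted p = 0.0016, and adipocyte markers for 6 of 7 genes, with a median of -2.11 and a camera adjusted p = 0.025. These 3 lists had an adjusted p = 0.749 with an estimated correlation. Where a probe was not well above background on any array of the dimmer gate, the signals of that gate were raised to at least the lowest signal well above background on their array, which gives a bound. By that bound, the globin gene Hbb-bh1, of a family with similar sequences, was at least 10.1-fold lower in Meis1-high, and the macrophage receptor gene Mrc1 at least 8.29-fold lower. Pan-leukocyte markers had a median of -0.89 (adjusted p = 0.234) and epithelial junction and keratin genes 0.37 (adjusted p = 0.303). Thymocyte markers had a median of -0.30 with an adjusted p = 0.960.

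No single gene passed the test between Meis1-high and Meis1-low. Limma called 0 of 18205 genes in each direction, with a smallest adjusted p = 0.249, and 2357 genes had an unadjusted p under 0.05 (854 higher, 1503 lower) where chance gives 910. Normexp background correction called 90 genes higher and 140 lower, and every other setting called 0. With slide as a block, all 15 called lists kept their call (adjusted p from 7.9e-08 to 0.032), whereas none was called with an estimated correlation or with the rotation test fry for one direction. Without Meis1-high replicate 2, the microfold-like (adjusted p = 0.0752), interferon (adjusted p = 0.0573) and adipocyte (adjusted p = 0.103) lists no longer passed.

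**Figure D2:**
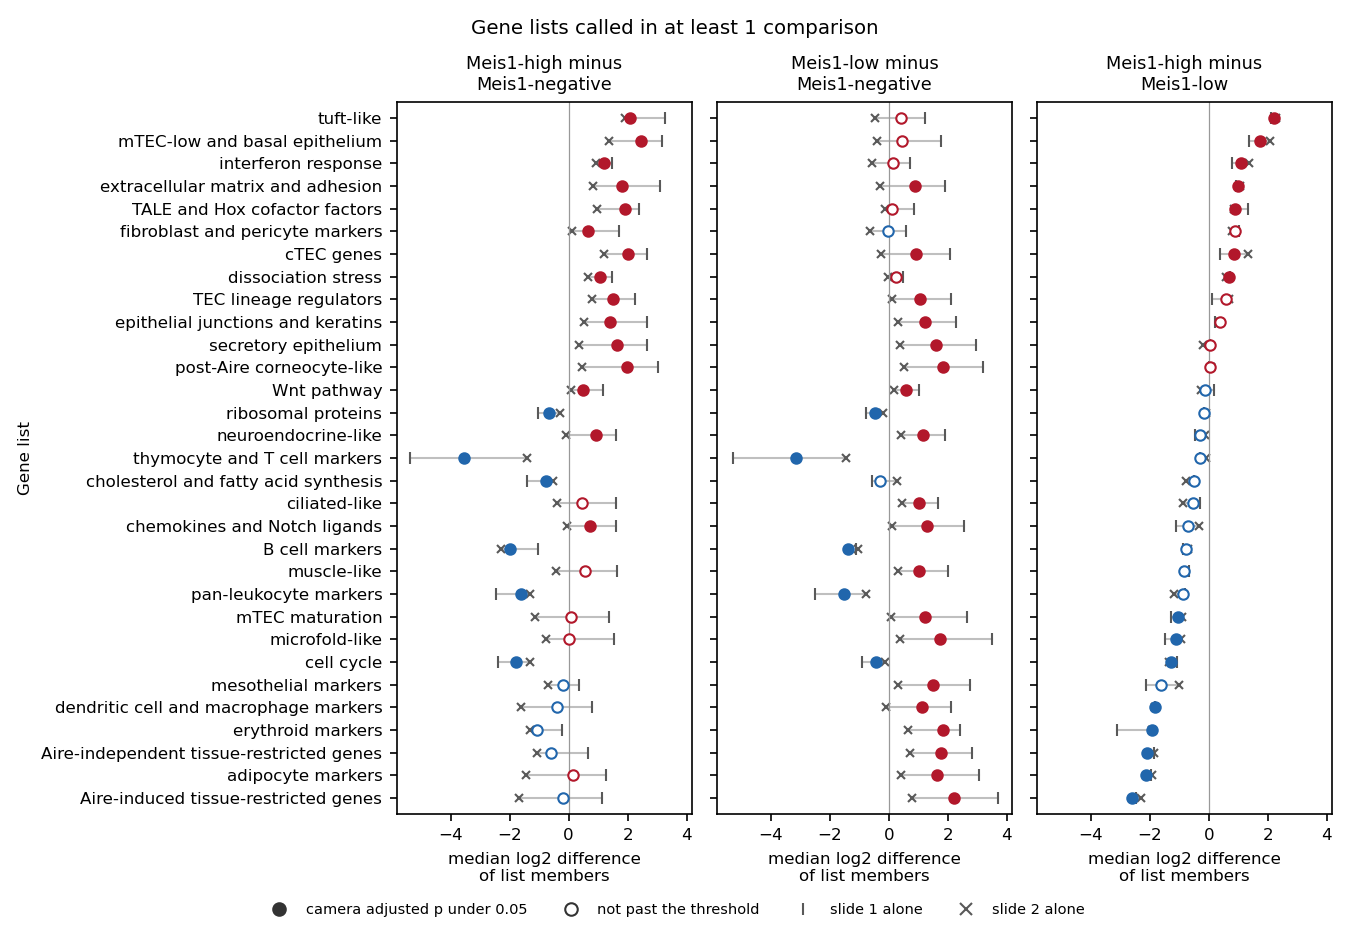
Median log2 difference of the members of each list called in at least 1 comparison, one panel per comparison, with red for higher and blue for lower. Filled circles passed the camera threshold and open circles did not, and ticks and crosses give slide 1 and slide 2 alone. Tuft-like genes lie above 2 on both slides between Meis1-high and Meis1-low, and thymocyte markers at -3.54 and -3.15 in the 2 comparisons with Meis1-negative.

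The comparison of Meis1-high with Meis1-negative cells asks what accompanies the reporter among small TEC. Epithelial genes of several kinds were higher in Meis1-high, and cell cycle genes and lymphocyte markers were lower, by camera at its preset correlation. With an estimated correlation, no list was called (smallest adjusted p = 0.627). All 32 cell cycle genes were lower on both slides, with a median log2 difference of -1.78 (SD over members 0.62), and all 19 cTEC genes were higher, with a median of 2.01 (SD over members 1.05). The thymocyte markers of Meis1-negative replicate 1 enter every value of this comparison, so each called list is given without that array too. Leaving it out does not free the comparison of leukocyte markers. On slide 2, Meis1-negative replicate 2 lay above the mean of the other gates by 1.24 for pan-leukocyte and 1.23 for B cell markers.

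Tuft-like genes rose in Meis1-high, 16 of 17 being higher, with a median of 2.06 (3.25 and 1.90 on the slides, 1.34 without Meis1-negative replicate 1 and 3.32 without replicate 2) and a camera adjusted p = 1.8e-08. Basal and mTEC-low genes rose with 14 of 15 higher, a median of 2.45 (3.18 and 1.37 on the slides, 1.44 without Meis1-negative replicate 1) and a camera adjusted p = 2.3e-08. Both lists had an adjusted p = 0.627 with an estimated correlation, and 7 and 8 members passed when adjusted over the list alone, against 0 over all genes tested. Trpm5 (chromosome 7, 150257715 to 150257774) differed by 4.23 ± 0.70 (SE, n = 2 per gate, adjusted p = 0.139 in limma), from 1.66 ± 0.24 (SD) in Meis1-high to -2.57 ± 1.05 in Meis1-negative. Dclk1 differed by 2.97 ± 0.69, Lifr by 3.03 ± 0.79, Ccl21a by 2.82 ± 0.79 and Krt14, the partner keratin of Krt5, by 2.84 ± 0.82, with adjusted p from 0.273 to 0.345.

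The cTEC list rose (2.65 and 1.19 on the slides, 1.03 without Meis1-negative replicate 1, camera adjusted p = 4.3e-09, adjusted p = 0.627 with an estimated correlation). Psmb11 (chromosome 14, 55245215 to 55245274) differed by 3.44 ± 1.20 (5.02 and 1.85 on the slides, 1.49 without Meis1-negative replicate 1), Igfbp5 by 2.69 ± 0.70 and Fgfr2 by 2.45 ± 0.69, and Ackr4, a scavenging chemokine receptor, was at least 5.95-fold higher. Extracellular matrix genes rose with 29 of 31 higher and a median of 1.81 (0.96 without Meis1-negative replicate 1, camera adjusted p = 5.2e-11), among them Lama3 at 3.20 ± 0.90. Epithelial junction and keratin genes rose with 26 of 27 higher and a median of 1.39 (0.52 without that array, camera adjusted p = 2.2e-07), although Epcam differed by 0.62 ± 0.78 (adjusted p = 0.803) and turned its sign without it. Corneocyte-like genes, of terminal skin differentiation, rose by a median of 1.98 (0.81 without that array, camera adjusted p = 3.2e-07) and secretory epithelial genes by 1.64 (0.56, camera adjusted p = 2.9e-05). TEC lineage regulators rose by a median of 1.51 (0.81, camera adjusted p = 3.9e-04), Trp63, the regulator of stratified epithelia, at 2.26 ± 0.80. TALE and Hox cofactor genes, Meis1 among them, rose by 1.90 (0.69, camera adjusted p = 0.0014), with Hoxa3 at 1.92 ± 0.62. Interferon response genes rose by 1.20 (0.48, camera adjusted p = 1.4e-04) and dissociation stress genes by 1.08 (0.47, camera adjusted p = 1.4e-04). Interferon response genes no longer passed without Meis1-high replicate 2 (0.97, adjusted p = 0.0594). For these 7 lists and the extracellular matrix, the adjusted p = 0.627 with an estimated correlation. Without Meis1-negative replicate 2, in contrast, the medians were larger, such as 2.60 for epithelial junctions and keratins, 2.68 for the extracellular matrix and 1.85 for the interferon response.

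Cell cycle genes fell in Meis1-high by -2.40 on slide 1 and -1.30 on slide 2 (-1.20 without Meis1-negative replicate 1, camera adjusted p = 3.3e-13, adjusted p = 0.627 with an estimated correlation). Nusap1, of the mitotic spindle, differed by -2.38 ± 0.65, and 2 members of the list passed when adjusted over the list alone. Thymocyte and T cell markers fell by a median of -3.54 (-5.36 and -1.39 on the slides, -1.57 without Meis1-negative replicate 1 and -5.33 without replicate 2), with 21 of 21 lower and a camera adjusted p = 2.0e-11. Pan-leukocyte markers fell by -1.63 (-1.46 without that array and -2.68 without replicate 2, camera adjusted p = 1.8e-08) and B cell markers by -1.97 (-2.40, camera adjusted p = 9.9e-05). The adjusted p = 0.627 with an estimated correlation for these 3 lists. Ptprc differed by -4.33 ± 0.90 (adjusted p = 0.227), the T cell factor gene Tcf7 by -3.90 ± 0.89 and the antibody heavy chain gene Ighm by -3.44 ± 0.66. The leukocyte surface genes Cd48 and Cd53 were at least 23.5-fold and at least 37.3-fold lower in Meis1-high, from levels on Meis1-negative replicates 1 and 2 of 2.30 and -0.43 for Cd48 and 2.85 and 0.35 for Cd53. Tissue-restricted genes of the Aire-induced list had a median of -0.19 (adjusted p = 0.410) and mTEC maturation genes 0.09 (adjusted p = 0.679), the latter with a mean of -0.43. Without Meis1-negative replicate 1 these lists passed as lower, at -1.65 (adjusted p = 2.9e-06) and -1.06 (adjusted p = 2.85e-06), whereas without replicate 2 the mTEC maturation list passed as higher, at 1.08 (adjusted p = 0.0347). Dendritic cell and macrophage markers did so as well, at -1.87 (adjusted p = 1.5e-07) against -0.39 with all arrays (adjusted p = 0.160), as did erythroid markers at -1.76 (adjusted p = 0.0058) against -1.06 (adjusted p = 0.183). The same held for Aire-independent tissue-restricted genes at -0.92 (adjusted p = 0.0299), against a median of -0.59 and a mean of 0.10 (adjusted p = 0.973), and for microfold-like genes at -0.92 (adjusted p = 0.0299) against 0.01 (adjusted p = 0.505).

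Ribosomal protein genes fell by a median of -0.65 (camera adjusted p = 7.1e-04, adjusted p = 0.809 with an estimated correlation) and cholesterol and fatty acid synthesis genes by -0.78 (camera adjusted p = 0.00137, adjusted p = 0.627 with an estimated correlation), with Idi1, an isoprenoid enzyme gene, at -2.16 ± 0.64. Wnt pathway genes rose by 0.50 (camera adjusted p = 0.0056, adjusted p = 0.646 with an estimated correlation) and neuroendocrine-like genes by 0.93 (camera adjusted p = 0.030, adjusted p = 0.787 with an estimated correlation). Chemokine and Notch ligand genes rose by 0.74 (camera adjusted p = 0.0197, adjusted p = 0.857 with an estimated correlation) and fibroblast and pericyte markers by 0.66 (camera adjusted p = 0.0286, adjusted p = 0.774 with an estimated correlation). Without Meis1-negative replicate 1, the ribosomal (-0.12), cholesterol (-0.70), Wnt (0.06), neuroendocrine (-0.15) and chemokine (-0.20) lists no longer passed. Without replicate 2, the ribosomal (-1.14), cholesterol (-1.34), Wnt (1.08) and chemokine (1.78) medians lay further from 0. The fibroblast list had a median of 0.41 without Meis1-negative replicate 1 (adjusted p = 0.0498). It had a median of 0.10 without Meis1-high replicate 1 and no longer passed (adjusted p = 0.508), nor without Meis1-negative replicate 2 (1.15, adjusted p = 0.108). Without Meis1-high replicate 2 it was 1.27, while the ribosomal (-0.52) and chemokine (0.52) lists no longer passed, and the neuroendocrine list did not without Meis1-high replicate 1 (0.89).

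Limma called 0 of 18205 genes in each direction between Meis1-high and Meis1-negative, with a smallest adjusted p = 0.123, and 1917 genes had an unadjusted p under 0.05 (1039 higher, 878 lower) where chance gives 910. Other settings called from 0 to 607 genes higher and from 0 to 346 lower, the most without Meis1-negative replicate 2, and normexp called 124 and 179. With slide as a block, the 21 called lists kept their call (adjusted p from 1.1e-13 to 0.0402).

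The comparison of Meis1-low with Meis1-negative cells asks how large TEC of intermediate reporter signal differ from small TEC without it. T cell and leukocyte markers were lower in Meis1-low, and corneocyte-like and tissue-restricted genes were higher, by camera at its preset correlation. With an estimated correlation, no list was called (smallest adjusted p = 0.685). All 21 thymocyte and T cell markers were lower on both slides, with a median log2 difference of -3.15 (SD over members 1.46), and all 22 corneocyte-like genes were higher, with a median of 1.85 (SD over members 0.76). The Meis1-negative arrays are those of the comparison with Meis1-high, so the 2 comparisons share their chance values.

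Thymocyte and T cell markers fell by -5.27 on slide 1 and -1.43 on slide 2 (-1.27 without Meis1-negative replicate 1, -5.48 without replicate 2, camera adjusted p = 2.3e-13). Pan-leukocyte markers fell by a median of -1.51 (-0.82 without that array and -2.56 without replicate 2, camera adjusted p = 1.2e-06) and B cell markers by -1.39 (-1.29 without it, camera adjusted p = 0.0106). These 3 lists had an adjusted p = 0.685 with an estimated correlation, and B cell markers no longer passed without Meis1-negative replicate 2 (-0.69, adjusted p = 0.0973) or with normexp (-0.13, adjusted p = 0.0737). Ptprc differed by -4.45 ± 0.90 (SE, n = 2 per gate, adjusted p = 0.391 in limma) and Cd3e by -5.78 ± 1.61, with -8.80 on slide 1 and -2.76 on slide 2 for Cd3e.

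Corneocyte-like genes rose by 3.18 on slide 1 and 0.50 on slide 2 (0.79 without Meis1-negative replicate 1, camera adjusted p = 3.2e-07), with the kallikrein gene Klk7 at 2.32 ± 0.79. Aire-induced tissue-restricted genes rose with 21 of 23 higher and a median of 2.23 (3.72 and 0.78 on the slides, 0.87 without that array, camera adjusted p = 4.5e-07). The liver genes Mup1, of a family with near-identical copies, and Apoh differed by 2.90 ± 1.05 and 2.46 ± 0.82. Aire-independent tissue-restricted genes rose by a median of 1.78 (0.90, camera adjusted p = 2.4e-05), Apoc3 at 1.90 ± 0.64 and Fabp9 at 2.96 ± 1.10. Microfold-like genes rose with 13 of 13 higher and a median of 1.75 (0.57, camera adjusted p = 5.0e-05), with Ccl6 at 2.86 ± 0.97, and secretory epithelial genes by 1.60 (0.66, camera adjusted p = 1.5e-05), with Scgb1a1 at 2.31 ± 0.88. Erythroid markers rose with 9 of 9 higher and a median of 1.84 (0.74, camera adjusted p = 8.7e-04), with Slc4a1, the red cell anion exchanger, at 2.69 ± 0.96. For these 6 lists, the adjusted p = 0.685 with an estimated correlation. Without Meis1-negative replicate 2 the medians of these 6 lists ranged from 2.48 for erythroid markers to 3.34 for microfold-like genes.

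Genes of mTEC maturation rose by a median of 1.25, 19 of 21 being higher (2.64 and 0.08 on the slides, camera adjusted p = 8.7e-04), but by 0.10 without Meis1-negative replicate 1 (adjusted p = 0.936). Aire differed by 1.72 ± 0.996 (adjusted p = 0.625), Cd80 by 2.15 ± 1.17 (adjusted p = 0.615) and Hdc by 1.87 ± 0.74 (adjusted p = 0.607). Epithelial junction and keratin genes rose by 1.24 (0.17 without that array), TEC lineage regulators by 1.05 (0.31), extracellular matrix genes by 0.88 (0.08) and chemokine and Notch ligand genes by 1.29 (-0.15). Neuroendocrine-like genes rose by 1.16 (0.46), ciliated-like genes by 1.01 (0.25), muscle-like genes by 1.02 (0.22) and Wnt pathway genes by 0.58 (0.24). Adipocyte markers rose by 1.63 (0.88) and mesothelial markers by 1.51 (0.61), while ribosomal protein genes fell by -0.48 (0.01) and cell cycle genes by -0.42 (0.04). For these 13 lists, the adjusted p = 0.685 with an estimated correlation, and none passed without Meis1-negative replicate 1. A further 2 lists likewise passed only with that array, rising with it, cTEC genes by 0.92 (-0.30, adjusted p = 0.731 with an estimated correlation) and dendritic cell and macrophage markers by 1.14 (-0.45, adjusted p = 0.714 with an estimated correlation). Camera's adjusted p of these 15 lists lay between 2.5e-05 and 0.0374. Without Meis1-negative replicate 2 the medians lay further from 0, such as 2.41 for mTEC maturation, 2.38 for epithelial junctions and keratins, 1.82 for TEC lineage regulators and 1.76 for the extracellular matrix. The same held for cTEC (1.65), chemokine (2.55), neuroendocrine-like (1.80), ciliated-like (1.73) and muscle-like genes (1.87), and for adipocyte (2.87), mesothelial (2.76) and dendritic cell and macrophage markers (2.57). Ribosomal genes had -0.96 and cell cycle genes -0.90 without it. Without Meis1-low replicate 1, TEC lineage regulators (0.92), cTEC (0.56), Wnt (0.64) and extracellular matrix genes (0.59) no longer passed either. Without Meis1-low replicate 2, calls were lost for ciliated-like (0.94), muscle-like (0.92), cell cycle (-0.55), Wnt (0.97) and ribosomal genes (-0.20) and for dendritic cell and macrophage markers (0.96). Tuft-like genes had a median of 0.40 (adjusted p = 0.867), and -0.59 without Meis1-negative replicate 1 (adjusted p = 0.0089), and interferon response genes 0.15 (adjusted p = 0.805), and -0.57 without it (adjusted p = 0.0062).

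Limma called 0 of 18205 genes in each direction between Meis1-low and Meis1-negative, with a smallest adjusted p = 0.0538, and 1473 genes had an unadjusted p under 0.05 (915 higher, 558 lower). Other settings called from 0 to 929 genes higher and from 0 to 339 lower, the most without Meis1-negative replicate 2, and normexp called 18 and 102. With slide as a block, the 24 called lists kept their call (adjusted p from 1.3e-12 to 0.0395).

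**Figure D3:**
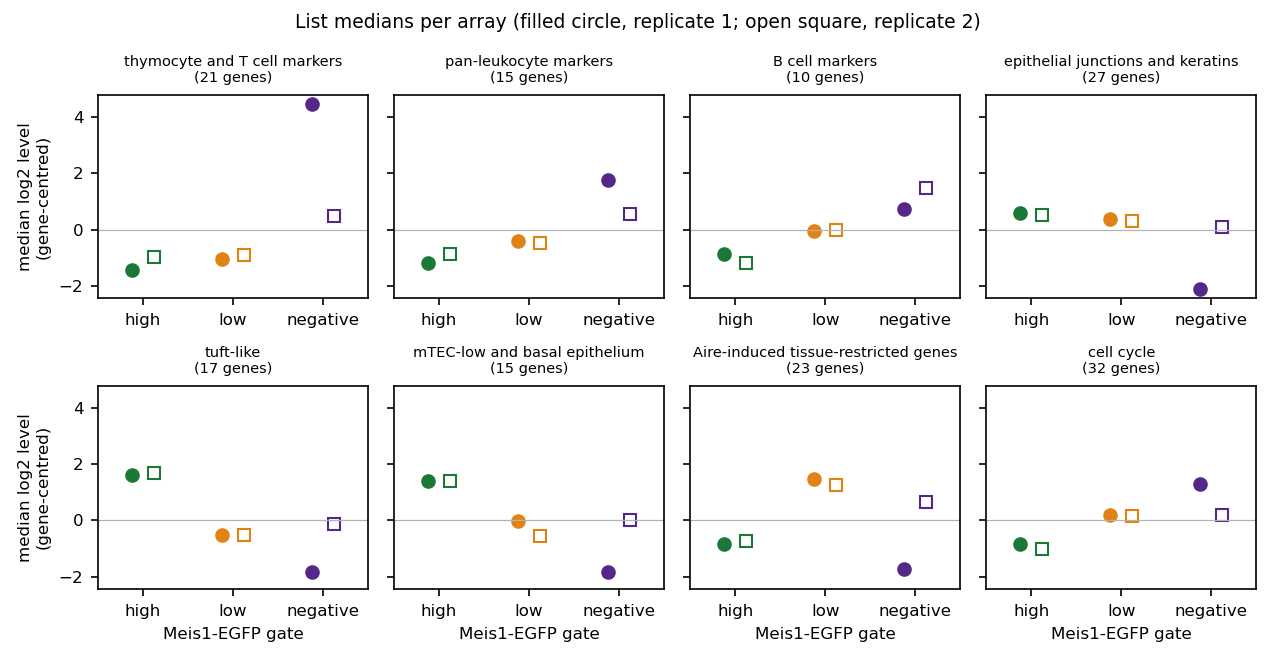
Median level of the members of 8 lists on each array, each gene centred on its mean over the arrays (log2), by gate. Filled circles are replicate 1 and open squares replicate 2. Thymocyte markers stand at 4.47 on Meis1-negative replicate 1 and 0.49 on replicate 2, and epithelial genes at -2.11 and 0.09.

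The order of the 3 gates was counted over all genes. The moderated F test of limma called 0 genes that differ among the gates, with a smallest adjusted p = 0.119, and 2086 genes had an unadjusted p under 0.05. Of these, 647 (31%) had the order Meis1-low, Meis1-negative, Meis1-high from highest to lowest, an order that 20.9% of all genes had. The order Meis1-high, Meis1-low, Meis1-negative was that of 353 (16.9%, against 15.5% of all genes). Genes with a probe well above background numbered 15197 and 18338 of 28030 in Meis1-high, 17710 and 19093 in Meis1-low, and 15155 and 19399 in Meis1-negative. The smallest exact two-sided p for 2 against 2 arrays is 0.33, so these counts were not tested.

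The remaining 8 lists were not called in any comparison in the reported setting, with all arrays and no block. Between Meis1-high and Meis1-low, Notch pathway genes had a median log2 difference of 0.82 (adjusted p = 0.0662, and 0.047 with slide as a block), NF-kB signalling genes -0.64 (adjusted p = 0.0859), oxidative phosphorylation genes -0.54 (adjusted p = 0.0502, and 0.032 with slide as a block) and MHC class I and immunoproteasome genes -0.45 (adjusted p = 0.243). TEC progenitor surface markers had a median of 0.52 (adjusted p = 0.310), endothelial markers -0.75 (adjusted p = 0.158), parathyroid and thyroid markers -1.05 (adjusted p = 0.293) and neural crest and Schwann markers -0.66 (adjusted p = 0.317). Between Meis1-high and Meis1-negative, oxidative phosphorylation genes had a median of -0.36 (adjusted p = 0.0644, and 0.0416 with slide as a block). NF-kB signalling genes passed there as lower without Meis1-negative replicate 1 (-0.71, adjusted p = 0.0047), as did oxidative phosphorylation genes as higher between Meis1-low and Meis1-negative (0.41, adjusted p = 0.0135). Between Meis1-high and Meis1-low, Notch pathway (adjusted p = 0.0265) and NF-kB signalling genes (adjusted p = 0.0333) passed without Meis1-negative replicate 1, and likewise without replicate 2. Oxidative phosphorylation genes passed there without Meis1-high replicate 1 (-0.69) or Meis1-low replicate 2 (-0.86), and Notch pathway genes without Meis1-high replicate 1 (0.95). Of the transcription factor genes named in advance, Foxn1, the master regulator of TEC, differed by -0.65 ± 0.75 (adjusted p = 0.755) and Meis2 by 0.06 ± 0.74 (adjusted p = 0.981).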

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

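The left-out arrays in the F test and the normexp and median scaling of the lists were added after the results were seen, and the other alternatives were planned. No gene was called as reported, and this count changed in the following settings. Between Meis1-high and Meis1-negative, normexp called 124 genes higher and 179 lower, median scaling 6 and 68, a floor 1 and 23, and a variance trend with robust fitting 0 and 4. Those 4, which the rule does not name and which were chosen after their values were seen, are Iglv1, Cd69 and 2 transcripts known by accession alone. Between Meis1-low and Meis1-negative, normexp called 18 higher and 102 lower, median scaling 0 and 13, and an adjusted p under 0.10 called 3 lower. Between Meis1-high and Meis1-low, normexp called 90 higher and 140 lower. With each array left out in turn, from 0 to 607 genes were higher and from 0 to 346 lower in Meis1-high than in Meis1-negative, from 0 to 929 and from 0 to 339 in Meis1-low than in Meis1-negative, 0 between Meis1-high and Meis1-low, and from 0 to 978 in the F test. All counts above 0 came without Meis1-negative replicate 2. That fit leaves 1 Meis1-negative array, assumed to vary like the other gates. The other alternatives called 0 genes.

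The Meis1 difference between Meis1-high and Meis1-negative was 1.08 with normexp (adjusted p = 0.589), and with arrays left out it ranged from 1.17 without Meis1-negative replicate 1 to 3.38 without Meis1-negative replicate 2, where alone it passed (adjusted p = 0.0453, range over alternatives 0.0453 to 0.997). Of the single genes followed through the alternatives, none called as reported, normexp called 28 of 46 between Meis1-high and Meis1-negative, 5 of 39 between Meis1-low and Meis1-negative and 23 of 55 between Meis1-high and Meis1-low. Median scaling called 3 of the 46, and leaving out Meis1-negative replicate 2 called 27 of the 46 and 16 of the 39.

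List calls fell from 21, 24 and 15 to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry's test of one direction, and ranged from 18 to 26, 12 to 26 and 13 to 18 with arrays left out. With slide as a block, 22, 24 and 17 lists were called, and no call was lost. Fry's test of change in either direction passed for B cell markers between Meis1-high and Meis1-negative (adjusted p = 0.0466) and for fibroblast markers between Meis1-low and Meis1-negative (adjusted p = 0.00099). Directions reversed in 8 cases. Without Meis1-negative replicate 1, the medians were -0.92 for microfold-like genes (1.25 without replicate 2) and -0.20 for chemokines (1.78) between Meis1-high and Meis1-negative. Between Meis1-low and Meis1-negative, they ranged from -0.30 to 1.65 for cTEC genes, from 0.10 (camera pointing lower) to 2.41 for mTEC maturation, from -0.15 to 2.55 for chemokines, and from -0.45 to 2.57 for dendritic cell markers, the first value without Meis1-negative replicate 1 and the second without replicate 2. Cell cycle genes had 0.044 without replicate 1 and -0.90 without replicate 2. Between Meis1-high and Meis1-negative, mTEC maturation passed as lower without replicate 1 (-1.06) and as higher without replicate 2 (1.08). Of the other list values, 1189 kept direction and side of the threshold, 44 newly passed and 163 no longer passed. Quantile scaling ended 1 call, that of dendritic cell and macrophage markers between Meis1-low and Meis1-negative, which left 23. It added 1 call between Meis1-high and Meis1-low. With normexp most medians shrank. It called 3 lists for Meis1-high and 2 for Meis1-low against Meis1-negative that were not called as reported. Between Meis1-high and Meis1-low it called 5 such lists. Between Meis1-high and Meis1-low all 15 calls held, with medians of 0.89 for tuft-like, 0.21 for TALE and Hox cofactor, -1.18 for Aire-induced and -0.79 for adipocyte genes. Against Meis1-negative, the thymocyte median was -1.81 for Meis1-high and for Meis1-low, the tuft-like median 0.90 for Meis1-high and the Aire-induced median 1.06 for Meis1-low. Normexp ended the calls of neuroendocrine-like genes (0.34) and chemokines (0.44) for Meis1-high against Meis1-negative, and for Meis1-low those of cTEC (0.50), neuroendocrine-like (0.61), ciliated-like (0.54) and muscle-like genes (0.53) and of dendritic cell (0.42) and B cell markers (-0.13). The tuft-like median between Meis1-high and Meis1-low ranged from 1.95 to 2.29 without single arrays. The cause was not tested. Weak signal limits Meis1-high replicate 1 and Meis1-negative replicate 1 most, with 53.1% and 54.2% of spots well above background.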

Other observations

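All tests in this part were chosen after the results were seen, the second thymocyte and tuft lists included. The random lists were drawn gene by gene. Their percentiles therefore do not allow for list members that vary together, nor for the spread between arrays. The first pattern is thymocyte transcripts on Meis1-negative replicate 1, which a sort for CD45-negative cells should have kept out. A candidate explanation is immature thymocytes in that pool. A second list of thymocyte genes, none of them on the first list, lay above replicate 2 by a median of 3.20, with 23 of 25 measured genes higher, at percentile 100 of matched random lists (which gave -1.25 to 0.45). On replicate 1, the probes with the strongest signals of the first list were those of Dntt (9.55), Cd3d (7.16) and Cd3e (6.82). On replicate 2 these stood at 3.17, 1.34 and 1.12, with Tcf7 (2.48) and Il7r (1.42) above Cd3d and Cd3e. Such levels give no order of abundance, since probes differ in affinity. Weak signal of the array is argued against by Meis1-high replicate 1, as weak, where the list lay at -0.056 from its replicate. For a sample without epithelial cells, 92.6% of the epithelial list (25 of 27 genes) was well above background. This mark cannot decide the question. Thymocyte markers were also well above background for 18 and 19 of 21 genes on Meis1-low replicates 1 and 2. Replicate 2 of Meis1-negative lay above the arrays of its own slide too, by 1.44 for the thymocyte list, and a biological difference between the gates stays open as untested.

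The second pattern is tuft-like genes higher in Meis1-high. Dilution of the Meis1-negative pools by leukocytes is argued against only for the median of 2.20 against Meis1-low, which uses no Meis1-negative array. Its part in the difference from Meis1-negative stays open. That median was 1.34 without Meis1-negative replicate 1 and 3.32 without Meis1-negative replicate 2. Dim genes reading higher are argued against by random lists of like mean level, which gave -0.77 to 0.59 between Meis1-high and Meis1-low. The percentile of 100 for the tuft-like list restates its high median, on which the pattern was chosen. More cells with a tuft-like program in the Meis1-high gate may explain the pattern. Between Meis1-high and Meis1-low, a second list of 27 other tuft cell genes had a median of 0.59 at percentile 99.61, with 19 genes higher. This percentile has the same limit, since tuft cell genes can vary together for other reasons than the gate. Of the bitter taste receptor genes, a family noticed in the values, 6 of 13 on the array were measured. Their median of 3.51 between Meis1-high and Meis1-low lay at percentile 100 of random lists, and that of 2.98 between Meis1-high and Meis1-negative at 99.99, which decides nothing for a family chosen on these values. Tas2r108, chosen after its values were seen, differed by 3.79 from Meis1-low (adjusted p = 0.249). Whether more cells or more transcript per cell underlies this was not tested.

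The third pattern is tissue-restricted genes and markers of several unrelated tissues higher in Meis1-low than in Meis1-high. Fibroblast and pericyte markers did not share it (median -0.88, Meis1-low minus Meis1-high). Dim genes reading higher on the Meis1-low arrays are argued against by random lists of like mean level, which gave -0.33 to 0.52. Both tissue-restricted lists together had a median of 2.31 (39 genes, 34 higher). Their percentile of 100 restates that median, on which the pattern was chosen. Blood cells in the Meis1-low gate stay open for the erythroid part, although a sort for EpCAM-positive CD45-negative cells should have removed them. The 3 haemoglobin genes had a median of 2.90 against 1.89 for the other erythroid genes, but Hbb-bt stood at 1.96 on Meis1-low replicate 2, 1.98 on Meis1-high replicate 2 and 2.65 on Meis1-negative replicate 2. A wide transcription of genes of other tissues stays open too. Meis1-low had more genes above a common level than the other arrays of its slide, but by as few as 40, where replicates differ by up to 2486. That largest difference is the one of Meis1-negative, across slides and with its deviating replicate 1, so it is a wide bar for an excess within a slide. On replicates 1 and 2 the counts were 15403 and 16747 in Meis1-low, 15202 and 16248 in Meis1-high, and 14221 and 16707 in Meis1-negative. The gates also differ in forward scatter, so cell size and reporter level cannot be separated for this pattern. The same holds for every other difference between Meis1-low and another gate, the tuft-like one included.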
